A study of Mus musculus with 16 samples.

How the data were processed

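RNA sequencing was analysed for 16 mouse libraries, 6 from sorted peritoneal B1b cells and 10 from whole aortas, all on the ApoE-deficient strain. The genotype label of each sample, wt or cre, set its group. The groups held 3 wild-type and 3 cre libraries of B1b cells, and 5 wild-type and 5 cre libraries of aorta. Replicate numbers follow the order of the samples within a group and pair nothing. The labels do not say that each sample came from a separate animal, so p-values measure the spread between these samples.

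Per the labels' protocols, aortas were frozen in liquid nitrogen and lysed in TRIzol, B1b cells were sorted from peritoneal lavage by surface markers that included low B220, high IgM and low CD5, RNA was purified with a Direct-zol kit, and libraries were made with the KAPA mRNA Hyperprep kit. CASAVA 1.8.2, STAR 2.5.2b and the mm10 build are named in the submitters' processing notes. The counting tool, the annotation release and the use of strand are not given in the sources used here. The deposited table holds raw read counts per RefSeq transcript, whole numbers that were not normalized by the authors, in 1 column per sample. Table columns were matched to samples by the sample titles.

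Of 35745 transcripts in the table, 35435 took a gene name from the RefSeq gene table, 193 took one from GENCODE and 117 took none. Transcripts without a name held 0.416% to 4.17% of the counts of a library. They stayed in library sizes and tests as entries of their own, 38 of those tested in B1b cells, of which 1 passed, and 39 of those tested in aortas, of which 0 passed (edgeR quasi-likelihood; 1683 entries there had an unadjusted p under 0.05). Transcripts of 1 gene shared reads. Of 4994 genes with at least 2 transcripts and at least 100 counts, 72.8% had a smallest transcript at 90% or more of the largest. Only the transcript of highest total count was therefore kept for each gene, which left 24562 entries, 24445 of them named genes. Gene coordinates are those of GRCm38, the assembly behind mm10. Ighm was not analysed here, nor were the lists of immunoglobulin constant regions and mitochondrial genome genes, which had no tested member.

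Counts per library after this step ran from 6815829 to 9911226 in B1b cells and from 1645926 to 7300894 in aortas. The 20 most abundant genes held 7.25% to 12.9% of the counts. Replicate pairs differed by far more than counting noise, with a chi-square per degree of freedom from 5.43 to 47.8 and a Pearson correlation of log2 CPM across genes from 0.877 to 0.989, so no library was treated as a repeat of another.

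Each tissue was fitted on its own with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by genotype, robust quasi-likelihood F test). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values used TMM-scaled library sizes. Intervals are 95% intervals of the log2 fold change, cre minus wild type. The design for B1b cells, the list members and the rule for naming genes were set before the data were examined. The plan assumed a table without aortas. The table held them, so the same design was applied to the aortas afterwards, and the aortic tests and the test of the difference between tissues, an interaction term over all 16 libraries, were chosen after the data were seen.

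Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for lists with at least 5 tested members. Of 30 lists set in advance, 25 could be tested in B1b cells and 27 in aortas. A further 15 lists were written after the leading genes had been seen, of which 11 and 15 could be tested. Camera with an estimated correlation and fry were run as alternatives. No list passed in either tissue with the estimated correlation. Counts of members past the threshold are given over all genes and adjusted over the list alone.

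Named genes followed a rule. Cd40, Cd5, Ptprc, Ighm and Apoe were always named. The 12 rising and 12 falling genes of largest absolute log2 fold change were taken among genes past the threshold whose groups did not overlap and whose mean reached 5 CPM, filled where too few passed by the genes of smallest p, which are said to have missed. Up to 4 members of smallest p and every member past the threshold were taken from each list. Predicted genes, microRNAs, small nucleolar RNAs and variable segments were counted and not named. In aortas the members were limited to 2 for each list past the camera threshold. Some genes that the rule takes in are not reported here, though they stay in the counts of genes. Genes named outside the rule are said to have been chosen after their values were seen.

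The scripts were tested on simulated counts drawn from the means and library sizes of the real samples. In the B1b design 51.5% of genes changed 1.5-fold, 80.6% of genes changed 2-fold and 96.8% of genes changed 4-fold were called, and 6.1% of 163 calls were false. In the aorta design the shares were 10.6%, 46.3% and 93.8%, and 4.8% of 104 calls were false. None of 30 unchanged lists was called in either design, and a list shifted 1.3-fold gave a camera adjusted p of 3.61e-09 in B1b cells and 0.000294 in aortas. Simulated genes were drawn independently of each other, so these list results do not cover lists whose members vary together. The estimated correlation of the real lists reached 0.82, for adipocyte markers in aortas.

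Alternatives were DESeq2 1.42.0, limma-voom with and without quality weights, edgeR without robust fitting, 3 other scalings, 2 other filters on low counts, an effect-size limit, the most abundant genes or other-cell markers left out, and each library left out in turn. Added after the data were seen were the transcript of lowest count per gene, every transcript tested, the 2 aortas under 2000000 counts left out, the heart muscle score as a covariate, and all alternatives of the test between tissues. Scores of a list in a library are means of log2 CPM with a pseudocount of 1. Bootstrap intervals used Python 3.11.15 and resampled the genes of a list, not the libraries, 10000 times.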

Results

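Gene expression was measured by RNA sequencing in 2 kinds of sample from ApoE-deficient mice, a strain prone to atherosclerosis. One kind was B1b cells, innate-like B cells sorted from peritoneal lavage, with 3 libraries labelled wild type and 3 labelled cre. The other was whole aorta, with 5 libraries of each label. The series describes the genotypes as wild type and B cell-specific deficiency of CD40, a costimulatory receptor of the TNF receptor family, and concerns the role of CD40 in keeping B1b cells. After 1 transcript was kept per gene, the B1b libraries held 7375650, 7811385 and 9209536 counts in wild type and 8310854, 6815829 and 9911226 in cre. The aortas held 4049173, 4615688, 6144901, 7141771 and 1979777 counts in wild type and 4050237, 1645926, 4275980, 7300894 and 6401439 in cre.

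The first comparison asked how B1b cells differed between the genotypes. Cd40 transcripts were not lower in the libraries labelled cre beyond the replicate spread. They stood at 36.8 ± 2.70 CPM in wild type and 32.8 ± 4.65 CPM in cre (SD, n = 3 each), a log2 fold change of -0.16 with a standard error of 0.14 and a 95% interval from -0.45 to 0.13 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.679). Cd40 lies on chromosome 2 from 165055614 to 165071654 in mm10. The altered part of the gene is not in the labels and the table gives 1 value per transcript, so these counts do not check the labels. The sort marker genes Ptprc and Cd5 did not pass, with Ptprc, the gene of B220, at a log2 fold change of 0.07 and Cd5 at -0.33. Apoe, the gene inactivated in the strain, stood at 8.35 CPM in wild type and 4.27 CPM in cre (edgeR adjusted p = 0.153).

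Several genes that cell activation or dissociation stress induces fell in cre B1b cells. Fosb, an AP-1 transcription factor, fell from 15.6 ± 1.2 to 4.35 ± 1.02 CPM (SD, n = 3 each), a log2 fold change of -1.84 (SE 0.25, edgeR quasi-likelihood adjusted p = 0.000588). Egr3, Gadd45b and Ppp1r15a, further stimulus-induced genes, fell by 0.89, 0.77 and 0.69 on the log2 scale. The calls of Gadd45b and Ppp1r15a ended in all 6 fits that left out a library (edgeR adjusted p from 0.0667 to 0.141 and from 0.0621 to 0.158). That of Egr3 ended in 5 of the 6 and in 4 of 12 alternatives. Cd69 and Cd83, surface markers of activated lymphocytes, fell by 0.75 and 0.65, and their calls ended in 2 and 3 of those 6 fits. The cytokine receptor genes Il21r and Il4ra fell by 1.14 (SE 0.14) and 0.66 (SE 0.10), Il21r from 58.7 ± 10.9 to 26.7 ± 0.909 CPM and Il4ra from 270.4 ± 35.2 to 171.5 ± 16.7 CPM (SD, n = 3 each). Rgl1, Akap12 and Serpinb1a fell by 1.2, 0.89 and 0.69. These genes code for an exchange factor of Ral GTPases, a scaffold of protein kinase A and an inhibitor of neutrophil proteases. The calls of Rgl1 and Akap12 ended in 3 and 4 of the 6 fits that left out a library.

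In the other direction, Jchain, the joining chain of secreted IgM, had the largest rise among the named genes past the threshold, from 4.52 ± 2.19 to 15.7 ± 2.71 CPM (SD, n = 3 each). Its log2 fold change was 1.78 (SE 0.30, edgeR quasi-likelihood adjusted p = 0.00678). Ccnd2, which encodes the G1 cyclin D2, rose from 415.1 ± 42.0 to 663.8 ± 67.7 CPM, a log2 fold change of 0.68 (SE 0.09, edgeR adjusted p = 0.000523). The myeloid genes Lyz1, a lysozyme, and Csf1r, the receptor of macrophage colony-stimulating factor, rose by 1.32 and 0.99 on the log2 scale. The call of Csf1r ended in 4 of the 6 fits that left out a library and in 2 of 11 alternatives. The cytokine receptor genes Il9r and Csf2rb2 rose by 0.88 and 0.85. Gda, a guanine deaminase, rose by 1.15, the lipid transporter gene Abca9 by 1.27, Slfn1 by 1.02, Serpina3f by 0.95, Raph1 by 0.85, Col27a1 by 0.84 and the noncoding transcript Gt(ROSA)26Sor by 1.48. With its transcript of lowest count Gt(ROSA)26Sor stood at 0.24 (edgeR adjusted p = 0.745), and its call ended without wild-type replicate 1 or cre replicate 2. Among the 6 fits that left out a library, the calls of Csf2rb2 and Abca9 ended in 5 and those of Slfn1 and Col27a1 in 4. That of Il9r ended in 2, and those of Lyz1 and Raph1 in 1 each. Lyz1, Serpina3f and Csf2rb2 have near-identical relatives, so reads counted for them are uncertain.

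**Figure D1:**
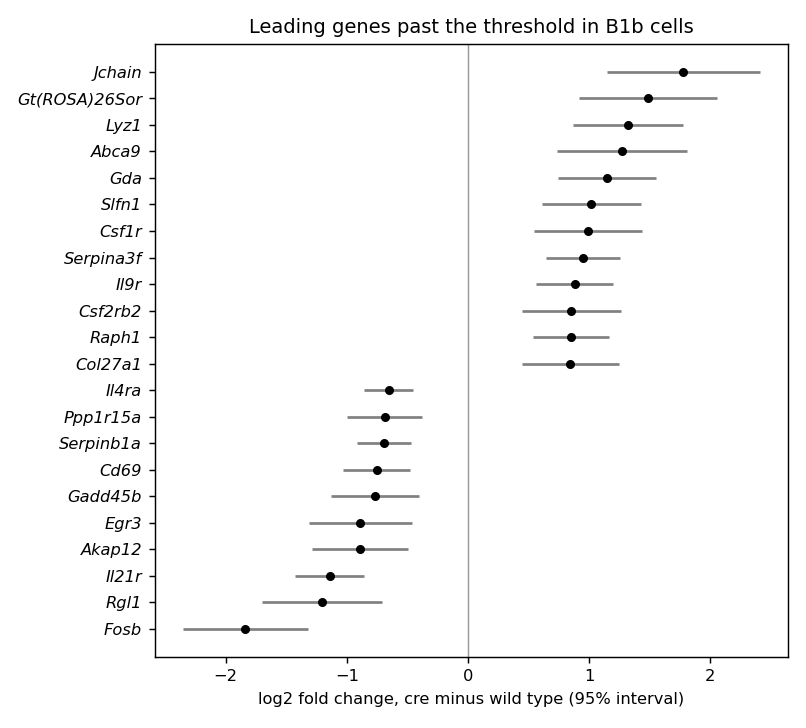
Log2 fold change, cre minus wild type, of 22 leading genes past the threshold in B1b cells (3 libraries per genotype), with points for the edgeR estimate and lines for the 95% interval. Estimates ran from 1.78 for Jchain to -1.84 for Fosb, and no interval reached 0.

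Of 11732 genes tested in B1b cells, 57 rose and 26 fell in cre (edgeR quasi-likelihood, adjusted over all genes). At an unadjusted p under 0.05 there were 1563 genes, 895 higher and 668 lower. The groups did not overlap for 2153 genes, 18.4% of those tested where chance gives 10%. Called genes numbered 196 by DESeq2 and 327 without the filter on low counts, against 35 without wild-type replicate 1, 36 without cre replicate 1 and 42 without cre replicate 2. Of the 83 genes, 30, 31 and 33 stayed past the threshold in those 3 fits, and all 83 kept their direction in each.

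Genes tied to CD40 itself were tested next. Of 25 tested genes of CD40 signalling and NF-kB, Traf5, an adaptor that binds TNF receptor family members, fell from 75.2 ± 11 to 53.9 ± 2.0 CPM (SD, n = 3 each), a log2 fold change of -0.48 (edgeR adjusted p = 0.0468). Its call ended in 3 of 12 alternatives and in 5 of 6 fits that left out a library (edgeR adjusted p up to 0.279 in the latter). The other 24 did not pass, among them Nfkbid at -0.49, Nfkbie at -0.32 and Nfkb1 at -0.18. Adjusted over the list alone, 3 were lower, and the median log2 fold change was -0.06 (camera adjusted p = 0.194). Of 26 tested genes that CD40 ligation raises in B cells, Cd69 and Cd83 fell, Ccnd2 rose and 23 did not pass, and 1 was higher and 5 lower adjusted over the list alone. The median was -0.07 (camera adjusted p = 0.277). Il4i1, an enzyme induced by interleukin 4 and CD40, stood at -0.62 without passing (edgeR adjusted p = 0.145).

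Several groups of B cell genes shifted lower in cre by camera with its preset correlation. Immediate early and dissociation stress genes had a median log2 fold change of -0.23 over 25 members (camera adjusted p = 0.000114, adjusted p = 0.479 with an estimated correlation), and of -0.15 without wild-type replicate 1. Fosb, Egr3 and Gadd45b fell, 22 members did not pass, and 1 was higher and 8 lower adjusted over the list alone. B cell receptor signalling had a median of -0.11 over 30 members (camera adjusted p = 0.00339, adjusted p = 0.479 with an estimated correlation). Over all genes 1 member fell, 29 members did not pass, and 7 were lower adjusted over the list alone. The adaptor gene Pik3ap1 stood at -0.42, the phosphatase gene Ptpn6 at -0.35 and the transcription factor gene Nfatc1 at -0.38. Markers of conventional B-2 cells had a median of -0.25 over 13 members (camera adjusted p = 0.00912, adjusted p = 0.645 with an estimated correlation). Il4ra fell, 12 members did not pass, and 5 were lower adjusted over the list alone. Fcer2a, which encodes the low-affinity IgE receptor CD23, stood at -0.93 and the follicle-homing receptor gene Cxcr5 at -0.25. Without cre replicate 3 the B-2 list no longer passed (camera adjusted p = 0.0887).

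MHC class II presentation had a median of -0.16 over 16 members (camera adjusted p = 0.0172, adjusted p = 0.645 with an estimated correlation). H2-Eb1, a beta chain of the class II molecule, fell from 2338 ± 101.8 to 1845 ± 57.6 CPM (SD, n = 3 each). Lgmn, an endosomal protease, fell by 0.53 on the log2 scale. The calls of H2-Eb1 and Lgmn ended in 4 and 5 of the 6 fits that left out a library. The remaining 14 members did not pass, and 1 was higher and 6 lower adjusted over the list alone. The camera call of the list held in 1 of those 6 fits, that without wild-type replicate 2 (the other fits gave camera adjusted p from 0.0512 to 0.12). Ribosomal protein genes had a median of -0.10 over 52 members, with 0 past the threshold over all genes (edgeR) and 1 higher and 3 lower adjusted over the list alone. Their camera adjusted p was 0.0172, with an adjusted p = 0.645 with an estimated correlation, 0.451 without wild-type replicate 1 and 0.215 without cre replicate 1. The median was -0.04 and -0.06 in those last 2 fits.

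Markers of macrophages and monocytes, cells that also live in the peritoneal cavity, were higher in the sorted cre cells. The median log2 fold change was 0.35 over 25 members (camera adjusted p = 0.0172, adjusted p = 0.645 with an estimated correlation, 0.123 without cre replicate 1), and the median was 0.64 without cre replicate 3. Lyz1 and Csf1r rose, 23 members did not pass, and 5 were higher and 2 lower adjusted over the list alone. Mitosis and G2/M genes had a median of 0.71 over 34 members, of which 0 passed over all genes (edgeR) and 4 were higher adjusted over the list alone. Cenpf, a kinetochore gene, stood at 2.06 (1.11 without cre replicate 3) and the spindle gene Tpx2 at 1.28. The camera adjusted p was 0.00143, with an adjusted p = 0.645 with an estimated correlation. The mean log2 CPM of the list was 3.44 in cre replicate 3 and 2.28 to 2.70 in the other 5 libraries, and without cre replicate 3 the median was 0.21 (camera adjusted p = 0.297).

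Lists on B-1 cell markers, antibody secretion and lipid metabolism did not pass in B1b cells. B-1 cell markers had a median of -0.02 over 20 members, with 0 genes past the threshold over all genes (edgeR) and 1 higher adjusted over the list alone. The tetraspanin gene Cd9 stood at 0.40 and Spn, the gene of CD43, at -0.57. Of 23 genes of plasma cells and antibody secretion Jchain alone rose, over all genes and adjusted over the list alone, and the median was -0.02 where mean and test were above 0 (camera adjusted p = 0.521). Of 25 genes of lipid handling and cholesterol efflux Cd36, a scavenger receptor, rose by 0.71, alone by both adjustments. The call of Cd36 ended in 4 of the 6 fits that left out a library. The median of that list was 0.02, where camera pointed lower (adjusted p = 0.862). Apoptosis and survival genes had a median of -0.03 over 27 members with camera pointing higher (adjusted p = 0.961). None passed over all genes (edgeR) and 2 were higher adjusted over the list alone, and the survival kinase gene Pim2 stood at 0.70 (edgeR adjusted p = 0.0568).

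**Figure D2:**
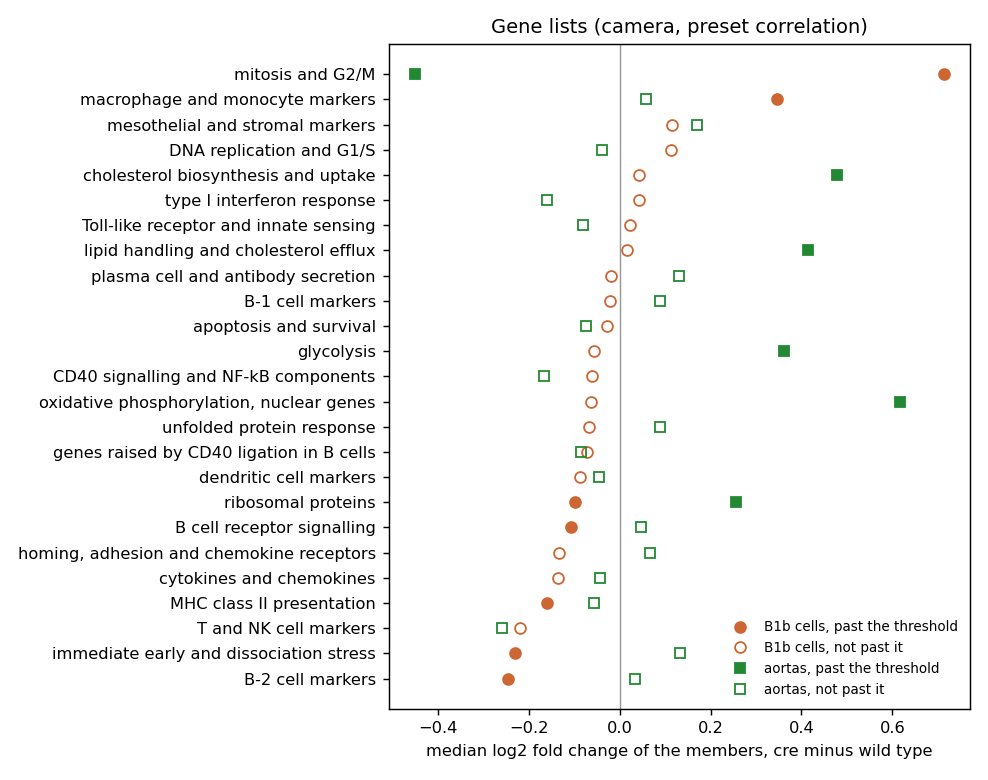
Median log2 fold change of the members of 25 gene lists, cre minus wild type, in B1b cells (circles, 3 libraries per genotype) and aortas (squares, 5 per genotype), filled where camera with a preset correlation passed. Mitosis and G2/M genes stood at 0.71 in B1b cells and -0.45 in aortas, and none of the filled points passed with an estimated correlation.

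The second comparison asked how the aortas differed between the genotypes. Fgf12, an intracellular fibroblast growth factor homologue of excitable cells, rose from 1.61 ± 0.538 to 11.7 ± 3.44 CPM (SD, n = 5 each), a log2 fold change of 2.91 (SE 0.35, edgeR adjusted p = 0.0105). Its call ended with limma-voom (adjusted p = 0.0507) and without wild-type replicate 1, wild-type replicate 3 or cre replicate 1 (edgeR adjusted p up to 0.0757). Cd79a, the gene of a B cell receptor chain, stood at 3.46 ± 1.29 CPM in wild type and 8.19 ± 12.3 CPM in cre, with 30.2 CPM in cre replicate 2, while Cd79b and Ms4a1 had log2 fold changes of 0.08 and 0.14. These 3 genes were chosen after their values were seen, and none passed (edgeR adjusted p = 0.594, 0.942 and 0.944). Cd40 stood at 7.33 ± 2.85 CPM in wild type and 5.57 ± 2.47 CPM in cre (SD, n = 5 each), a log2 fold change of -0.35 (95% interval from -1.12 to 0.43, edgeR adjusted p = 0.711). Ptprc, expressed by leukocytes in general, stood at -0.48, and Apoe stood at -0.12.

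**Figure D3:**
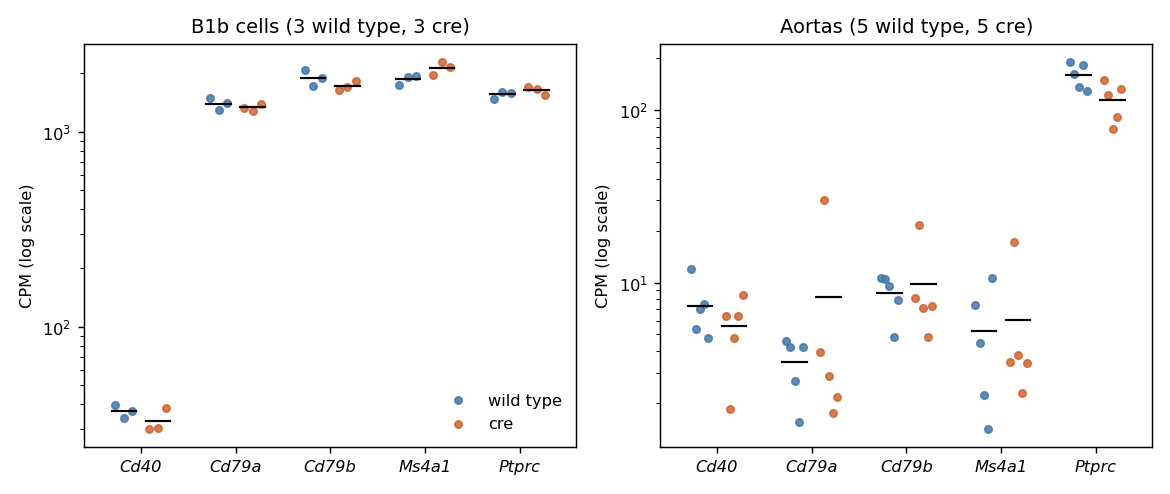
CPM on a log scale of Cd40, Cd79a, Cd79b, Ms4a1 and Ptprc in each library, with bars for the group mean, in B1b cells (left, 3 libraries per genotype) and aortas (right, 5 per genotype). Cd40 overlapped between the genotypes in both tissues, and none of the 5 genes passed in either.

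Of 13364 genes tested in aortas, 2 rose and 0 fell (edgeR quasi-likelihood). At an unadjusted p under 0.05 there were 918 higher and 765 lower genes, DESeq2 called 127 higher and 77 lower, limma-voom called 1 higher and 0 lower, and limma-voom with quality weights called 9 higher and 0 lower. The groups did not overlap for 389 genes, 2.9% where chance gives 0.79%. The count was 0 without wild-type replicate 1, wild-type replicate 3 or cre replicate 1, was 1 without wild-type replicate 2, cre replicate 2 or cre replicate 5, and was 14 without cre replicate 4. It was 92 without the 2 libraries under 2000000 counts.

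Genes of heart muscle led those that missed the threshold in aortas. Myl7, an atrial myosin light chain, stood at 33.9 ± 8.25 CPM in wild type and 367.2 ± 180.9 CPM in cre (SD, n = 5 each), a log2 fold change of 3.44 (SE 0.47, edgeR adjusted p = 0.0934). Another atrial light chain gene, Myl4, stood at 3.24, the calcium pump regulator gene Sln at 3.8, Mybphl at 3.59 and Sbk3 at 3.34. Also among the leading genes that missed were Myl1 at 1.75, Mgst3 at 0.93, Ndufs6 at 0.83 and Igfbp6 at 0.78. On the lower side Zmym6 stood at -0.75, Trp53inp1, a target of p53, at -1.0 and Xist, the noncoding RNA of X inactivation, at -0.68. Napepld, Smg1, Tsc22d2, Abi3bp, AW549877, Ncapg2, Fam76b and Kirrel stood between -0.98 and -0.61, and edgeR adjusted p of these 11 lower genes ran from 0.100 to 0.156.

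The list of atrial and shared heart muscle markers, written after these genes were seen, had a median log2 fold change of 0.99 over 23 members (camera adjusted p = 3.6e-08, adjusted p = 0.618 with an estimated correlation). None passed over all genes (edgeR) and 7 were higher adjusted over the list alone. The mean log2 CPM of the list was 7.05 to 8.04 in cre replicates 1, 2, 3 and 5, 5.37 in cre replicate 4 and 4.99 to 6.70 in wild type. Skeletal muscle markers had a median of 2.31 over 12 members, 7 of them higher adjusted over the list alone (camera adjusted p = 2.03e-06, adjusted p = 0.507 with an estimated correlation). Without cre replicate 1 the median was 1.34. Tnnt3, a fast troponin T, reached 155.7 CPM in cre replicate 1 and 3.71 to 38.9 CPM in the other cre aortas. Nerve and Schwann cell markers had a median of 1.96 over 15 members, 8 of them higher adjusted over the list alone (camera adjusted p = 2.55e-07, adjusted p = 0.507 with an estimated correlation). Mapk10, a neuronal kinase gene, stood at 2.91 and the splicing factor gene Rbfox1 at 1.74. The mean log2 CPM of that list was 6.58 in cre replicate 4 and 2.84 to 4.60 in the other 9 aortas, and its median was 1.12 without cre replicate 4 and 2.96 without cre replicate 1. None of the members of these 3 lists passed over all genes tested.

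**Figure D4:**
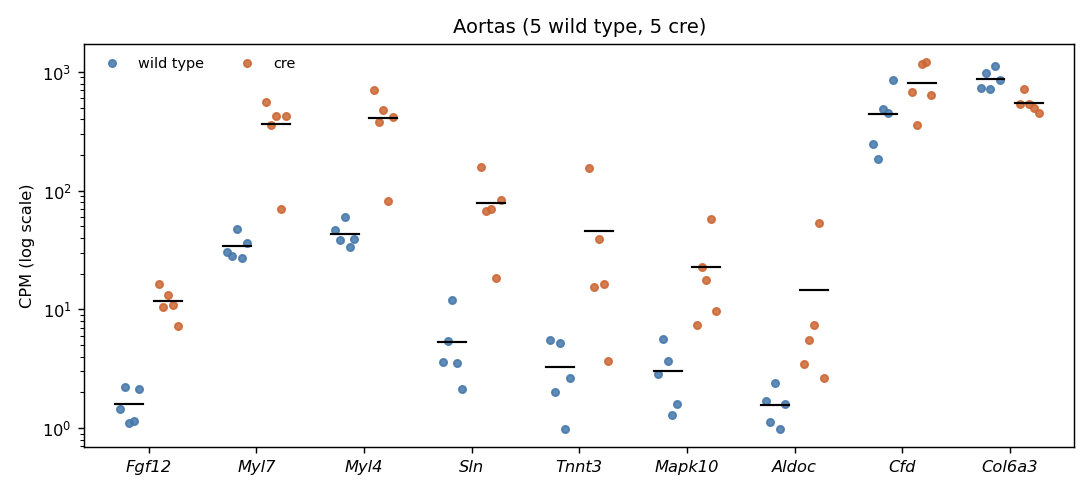
CPM on a log scale of 9 genes in each aorta (5 wild type, 5 cre), with bars for the group mean. Fgf12 rose in cre, while the muscle genes Myl7, Myl4 and Sln and the neuronal kinase gene Mapk10 stood higher in cre without passing. Tnnt3 reached 155.7 CPM in cre replicate 1 against 3.71 to 38.9 CPM in the other cre aortas. Aldoc reached 53.8 CPM in cre replicate 4 against 2.63 to 7.35 CPM.

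Genes of energy metabolism were higher in cre aortas by camera. All 49 nuclear genes of oxidative phosphorylation had a log2 fold change above 0, with a median of 0.62 (camera adjusted p = 3.82e-25, adjusted p = 0.809 with an estimated correlation). None passed over all genes (edgeR), and 37 were higher adjusted over the list alone. Ndufb10, a complex I subunit, stood at 0.70 and Uqcrq, a complex III subunit, at 0.78. The mean log2 CPM of the list was 7.135 to 7.503 in cre replicates 1, 3, 4 and 5 and wild-type replicate 5, and 6.319 to 6.787 in the other 5 aortas. Heart muscle markers stood at 8.01, 7.97 and 8.04 in cre replicates 1, 3 and 5, and at 5.37 and 5.76 in cre replicate 4 and wild-type replicate 5. Adipocyte markers stood at 8.39, 8.26 and 8.09 in cre replicate 4, wild-type replicate 5 and cre replicate 3, and at 7.31 and 7.07 in cre replicates 1 and 5. Brown fat markers stood at 6.348, 6.472 and 6.196 in the former 3 and at 5.266 and 5.101 in the latter 2. Glycolysis genes had a median of 0.36 over 19 members, 3 of them higher adjusted over the list alone (camera adjusted p = 0.000141, adjusted p = 0.809 with an estimated correlation). Tpi1 stood at 0.49, and Aldoc stood at 3.26 with 53.8 CPM in cre replicate 4, without which it stood at 1.57. Ribosomal protein genes had a median of 0.26 over 45 members, 0 of them past the threshold by either adjustment (camera adjusted p = 4.51e-09, adjusted p = 0.809 with an estimated correlation). Rpl37 stood at 0.45 and Rps14 at 0.52.

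Lipid gene lists were also higher in cre aortas by camera, and the list of mitosis and G2/M genes was lower. Lipid handling and cholesterol efflux had a median of 0.41 over 29 members (camera adjusted p = 0.00542, adjusted p = 0.953 with an estimated correlation). Fabp5, a fatty acid binding protein, stood at 0.72 and the lipid droplet gene Plin2 at 0.60. The mean log2 CPM of the list was highest in cre replicate 4, wild-type replicate 5 and cre replicate 3 (8.17, 7.95 and 7.93), and so was that of adipocyte markers (8.39, 8.26 and 8.09), a list that shares 3 genes with it. The other 7 aortas reached at most 7.44 and 7.31. As each library was left out, the median of lipid handling ran from 0.16 to 0.62. Cholesterol biosynthesis and uptake had a median of 0.48 over 24 members (camera adjusted p = 0.00701, adjusted p = 0.953 with an estimated correlation), with Dhcr7 at 0.65 and Acat2 at 0.80 (0.30 and 0.43 without cre replicate 4). Without cre replicate 4 these medians were 0.16 and 0.12 (camera adjusted p = 0.0848 and 0.511). The lipid handling call also ended without wild-type replicate 1 (camera adjusted p = 0.0876), and the cholesterol call without wild-type replicate 3 (camera adjusted p = 0.0684). Mitosis and G2/M genes had a median of -0.45 over 38 members (camera adjusted p = 2.98e-06, adjusted p = 0.809 with an estimated correlation), with Cenpf at -0.84 and Anln at -0.72. No member of these 3 lists passed over all genes (edgeR) or adjusted over the list alone. DNA replication and G1/S genes did not pass, with a median of -0.04 over 36 members (camera adjusted p = 0.56). At least as many of the lists set in advance passed in 45 of 60 splits of the aortas, the real one included.

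The 15 lists written later held 5 others that passed in aortas with the preset correlation and not with the estimated one. Adipocyte markers had a median of 0.62 (camera adjusted p = 0.00198, 0.0613 without wild-type replicate 1, adjusted p = 0.734 with an estimated correlation). The median was 0.31 without cre replicate 4 and 1.19 without wild-type replicate 5. Retn stood at 0.99 and the adipsin gene Cfd at 0.87. Brown fat markers had a median of 0.36 (camera adjusted p = 0.0139, adjusted p = 0.734 with an estimated correlation), with Cox7a1 at 1.16 and Cox8b at 1.06. That call ended without wild-type replicate 1, cre replicate 3 or cre replicate 4 (camera adjusted p = 0.126, 0.0723 and 0.168), and the median ran from 0.15 without cre replicate 4 to 1.06 without wild-type replicate 5. Endothelial markers had a median of 0.18 (camera adjusted p = 0.0139, adjusted p = 0.618 with an estimated correlation), with Esam at 0.46 and Cldn5 at 0.49, and the call ended without wild-type replicate 1, cre replicate 3 or cre replicate 5 (camera adjusted p = 0.0752, 0.0744 and 0.119). Its median ran from 0.11 to 0.33 as each library was left out. Foam cell and plaque macrophage genes had a median of 0.20 (camera adjusted p = 0.00731, adjusted p = 0.734 with an estimated correlation), and the call ended without wild-type replicate 1, wild-type replicate 5 or cre replicate 5 (camera adjusted p = 0.0621, 0.198 and 0.119). That median ran from 0.12 to 0.38 as each library was left out. Fibroblast and extracellular matrix genes had a median of -0.45 over 23 members, 13 of them lower adjusted over the list alone (camera adjusted p = 3.11e-08, adjusted p = 0.507 with an estimated correlation). The collagen genes Col6a3 and Col5a2 stood at -0.68 and -0.61.

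A further test asked whether the difference between the genotypes itself differed between B1b cells and aortas. Of 15091 genes tested over all 16 libraries, 3 passed (edgeR quasi-likelihood). For Raph1, a regulator of actin dynamics, the difference was -1.30 (SE 0.20), with 0.85 in B1b cells and -0.46 in aortas. For Rgl1 it was 1.52 (SE 0.23), with -1.2 in B1b cells and 0.31 in aortas. DESeq2 called 173 genes. The count fell to 1 without any 1 of wild-type replicates 1 and 3 and cre replicates 1, 2 and 3 of the B1b cells. Neither Raph1 (edgeR adjusted p from 0.0553 to 0.134) nor Rgl1 (edgeR adjusted p from 0.057 to 0.136) passed in those 5 fits. Rgl1 also did not pass with limma-voom (adjusted p = 0.149) or without wild-type replicate 2 of the B1b cells or wild-type replicate 1 or 2 of the aortas (edgeR adjusted p = 0.0981, 0.0581 and 0.0526). The count was 6 without aortic wild-type replicate 3 and 7 without aortic cre replicate 4.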

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

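Both the aortic comparison and the test of the difference between tissues were added after the data were seen, and no further test of this part was chosen only after the result was seen. The difference between genotypes differed between B1b cells and aortas for 3 genes, among them Raph1 (by -1.30 on the log2 scale) and Rgl1 (by 1.52). Of 60 splits drawn at random within each tissue, the real one included, only 1, the real split, gave as many as 3 genes. The highest other split gave 1. Labels were exchanged in both tissues together, which also breaks up any genotype difference that the tissues share. These splits therefore cannot decide whether the difference between the tissues itself arose by chance. Without any 1 of 5 of the 6 B1b libraries the count was 1, and neither Raph1 nor Rgl1 passed.

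The number of genes called in aortas was not set apart from chance. Of 60 drawn splits of the 10 aortas, the real one included, 3 gave at least 2 genes, and the highest other split gave 198. That split set wild-type replicates 1, 2, 3 and 4 with cre replicate 2 against the other 5 aortas, so it differs from the genotype split only by the exchange of cre replicate 2 and wild-type replicate 5, the 2 libraries under 2000000 counts. It is therefore not free of any genotype difference. For the lists, 45 of 60 splits, the real one included, gave at least 6, and the highest other split gave 18. In B1b cells there are only 10 splits of the 6 libraries, too few for a share under 0.05. The real split gave 83 genes and the highest other 5, and the real split gave 7 lists, as did the highest other, so 2 of 10 splits gave at least 7.

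Single cre aortas stood far from the other 4 for 5 named genes, by the gap to the nearest value divided by the whole range. The test was run on 96 groups of 5 and marks about 1 in 20 by chance where groups are independent and values normally distributed. The 5 flags are about as many as that rate gives. Many of these genes were named by their values in the same aortas and the groups share libraries, so the rate is only a rough guide. In cre replicate 4 Aldoc stood at 53.8 CPM against 2.63 to 7.35 (ratio 0.908). There Dhcr7 stood at 43.6 CPM against 17.9 to 21.0 (ratio 0.877). Rbfox1 stood at 30.5 CPM in that library against 8.66 to 12.1 (ratio 0.844). In cre replicate 3 Ndufb10 stood at 212.3 CPM against 159.7 to 165.8 (ratio 0.885). In cre replicate 1 Tnnt3 stood at 155.7 CPM against 3.71 to 38.9 (ratio 0.768).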

How the results depend on the processing

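Alternatives for the aortas, for the lists added later and for the test between tissues, and those on transcripts, shallow libraries and heart muscle, were chosen after the data were seen. In B1b cells the 83 called genes became 196 (133 higher, 63 lower) with DESeq2, 327 (226 higher, 101 lower) without the filter on low counts and 13 (9 higher, 4 lower) at an absolute log2 fold change of at least 1. They numbered 35 to 103 as each library was left out. The other 11 alternatives gave counts within 1.5 times. All 83 kept their direction under the other scalings, filters and tools, and 82 of 83 did so with the transcript of lowest count per gene. Of the 28 named genes past the threshold in B1b cells, 17 stayed past it in every alternative on normalization, filter, test and transcript, and 8 did so also without each library (Jchain, Gda, Serpina3f, Fosb, Il21r, Serpinb1a, Il4ra and Ccnd2). Cd40 kept its sign and did not pass in any alternative in either tissue, and as each library was left out it ran from -0.28 to -0.09 in B1b cells and from -0.54 to -0.11 in aortas. Cd5 in B1b cells ran from -0.78 to 0.0306 and Apoe in aortas from -0.28 to 0.0115 as each library was left out. The 7 lists past the threshold in B1b cells became 0 with an estimated correlation, 2 with fry and 4 to 8 as each library was left out. Fry kept B cell receptor signalling (adjusted p = 0.0444) and added T and NK cell markers. The 1 later list became 0 with the estimated correlation and 0 with fry, and was 1 to 2 as each library was left out. In aortas the 2 called genes became 204 with DESeq2, 1 with limma-voom, 9 with quality weights, 6 without robust fitting, 1 with the transcript of lowest count, 92 (79 higher, 13 lower) without the shallow libraries and 166 (142 higher, 24 lower) with the heart muscle score, and 0 to 14 as each library was left out. With that score as covariate the atrial gene Myl7 still stood at 2.20 and passed (edgeR adjusted p = 0.00451). The score therefore did not remove the heart muscle difference. The 6 lists in aortas became 0 with the estimated correlation and 0 with fry, and 5 to 9 as each library was left out. The 8 later lists became 0 with the estimated correlation and 0 with fry, and 4 to 10 as each library was left out. Of the 3 genes that differed between tissues, DESeq2 gave 173, limma-voom 2 and the left-out fits 1 to 7. The cause of these changes was not tested. Leaving out a library leaves fewer samples, yet the count in B1b cells rose to 101 without wild-type replicate 3 and to 103 without cre replicate 3. No paired analysis was possible because the labels carry no number shared between the genotypes. The aortas of 1645926 and 1979777 counts limit what low genes can show, and in simulated aortas 46.3% of genes changed 2-fold were called.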

Other observations

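The lists on interferon gamma, Notch, monocytes, macrophages and tissue types were written after the leading genes were seen, and the tests chosen only after the result was seen were those of large peritoneal macrophages and of expression by B1b cells themselves. In B1b cells 5 of 25 tested genes inducible by interferon gamma rose in cre, 20 did not pass, and 6 were higher and 3 lower adjusted over the list alone. The guanylate-binding protein genes Gbp2, Gbp3 and Gbp7, which act in defence against intracellular microbes, rose by 0.67, 0.60 and 0.83 on the log2 scale, Gbp2 from 195.5 ± 3.27 to 310.1 ± 22.5 CPM (SD, n = 3 each). The serpin genes Serpina3f and Serpina3g rose by 0.95 and 0.63. These families have near-identical members, so counts for single genes are uncertain. The median of the list was 0.01 and the mean 0.17, with 13 of 25 members above 0, and the list passed neither with camera (adjusted p = 0.446) nor with fry (adjusted p = 0.131). Dtx1, a Notch target in B cells, fell by 0.62 (edgeR adjusted p = 0.0108), while the 8 Notch targets had a median of -0.10 (camera adjusted p = 0.571). Gbp2, Gbp3, Gbp7, Serpina3g and Dtx1 were chosen after their values were seen.

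Other gene groups in B1b cells did not pass camera. Oxidative phosphorylation had a median of -0.06 over 48 genes (adjusted p = 0.0704), glycolysis -0.06 (0.19), the unfolded protein response -0.07 (0.435), DNA replication and G1/S 0.11 (0.277) and cholesterol biosynthesis and uptake 0.04 (0.793). The glycolytic gene Aldoa stood at -0.36 (edgeR adjusted p = 0.0588). Type I interferon response genes had a median of 0.04 with Slfn1 alone past the threshold over all genes (camera adjusted p = 0.435), innate sensing 0.02 (0.961) and homing, adhesion and chemokine receptors -0.13 (0.342), where Selplg, the gene of a selectin ligand, stood at 0.35. Cytokines and chemokines had a median of -0.13 and a mean of 0.10 with the test pointing lower (camera adjusted p = 0.96), and Ccl9 stood at 1.39. Among other cell types, T and NK cell markers had a median of -0.22 over 9 genes (camera adjusted p = 0.277), dendritic cell markers -0.09 (0.521) and mesothelial and stromal markers 0.11 (0.342). Adjusted over the list alone, the unfolded protein response had 2 members lower, glycolysis 1 lower, type I interferon response 2 higher, homing receptors 1 higher and 1 lower, cytokines 1 higher and mesothelial and stromal markers 1 higher, and the other lists of this paragraph set in advance had 0 (edgeR). Among the later lists, skeletal muscle stood at -0.48 (0.118), smooth muscle at -0.14, adipocytes at -0.11, nerve at -0.06 and extracellular matrix at 0.01 (each 0.571), foam cell genes at 0.15 (0.341) and pan-B cell genes at -0.09 (0.159).

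In aortas the gene groups of this paragraph, most of them immune, did not pass camera, unlike the foam cell and plaque macrophage genes above. CD40 signalling and NF-kB had a median of -0.17 (adjusted p = 0.0585), genes raised by CD40 ligation -0.08 (0.807), macrophage and monocyte markers 0.06 with a mean of -0.01 (0.835), T and NK cell markers -0.26 (0.55), granulocyte and mast cell markers 0.21 (0.219) and type I interferon response -0.16 (0.328). B-1 cell markers stood at 0.09 (0.55), plasma cell genes at 0.13 (0.171), B cell receptor signalling at 0.05 (0.867) and innate sensing at -0.08 (0.542). Median and test differed in sign for B-2 cell markers (0.03, 0.758), MHC class II (-0.06, 0.867), homing receptors (0.07, 0.835), cytokines (-0.04, 0.693) and dendritic cell markers (-0.04, 0.807). Apoptosis stood at -0.07 (0.328), DNA replication at -0.04 (0.56), the unfolded protein response at 0.09 (0.693), immediate early genes at 0.13 (0.219), erythrocyte and platelet markers at 0.12 (0.55) and mesothelial and stromal markers at 0.17 (0.673), of which 6 were higher and 6 lower adjusted over the list alone. By that adjustment B cell receptor signalling had 1 member higher, and the other lists above had 0 (edgeR). Of the later lists, smooth muscle contractile markers stood at -0.07 (0.0895), pan-B cell genes at 0.11 (0.852), interferon gamma genes at -0.17 (0.344), monocyte genes at 0.23 (0.102) and large peritoneal macrophage genes at 0.15 (0.852). Ventricular markers had a median of 0.27 and Notch targets 0.15 with tests pointing lower (0.416 and 0.852).

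Of the 83 genes called in B1b cells, 79 were tested in aortas, and 26 of them had a log2 fold change of the same sign there. At an unadjusted p under 0.05 in aortas, 0 of the 79 had the same sign and 10 the opposite one (edgeR). Over all 13364 genes tested in aortas 1683 had such a p, so the share among the 79 was near that of all genes. The split between the signs was not tested. Every library held at least 1160 counts of Xist, and the 4 genes of the Y chromosome, Ddx3y, Eif2s3y, Kdm5d and Uty, together held 0 counts in 15 libraries and 1 count in the other.

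Myeloid genes were higher in cre B1b libraries, and monocyte-like cells among the sorted cells are a candidate explanation. The 28 tested monocyte and small peritoneal macrophage genes had a median log2 fold change of 0.66 (bootstrap 95% interval over the genes 0.18 to 1.09). That interval treats the genes as independent and leaves out the spread between libraries. This list gave a camera adjusted p of 5.07e-06 (adjusted p = 0.63 with an estimated correlation) and 6 members higher and 0 lower adjusted over the list alone, while 0 passed over all genes (edgeR) and 13 were higher at an unadjusted p under 0.05. Wild-type B1b libraries also held 20 of the 28 genes at 5 CPM or more, 5 of the 28 stand in another list, and the most abundant members moved little, Psap from 1442 to 1393 CPM and Cybb from 599.9 to 686.6 CPM. In the list of macrophage and monocyte markers set in advance, the most abundant member, Fn1, stood at 140.8 CPM in wild type and 314.3 CPM in cre without passing. The next, Ctsd, stood at 115.2 and 112.6 CPM. Fn1 and Ctsd were chosen after their values were seen. The mean log2 CPM of the monocyte list was 4.57 to 4.79 in cre and 3.63, 4.08 and 4.42 in wild type, lowest in wild-type replicate 1. The sort selected for high IgM, and how far that removed such cells was not measured here. Large peritoneal macrophages (median 0.11, bootstrap 95% interval -0.28 to 0.59 over 13 genes, 5 of them at 5 CPM or more in wild type and 9 in another list, the most abundant being Icam2 at 50.9 CPM in wild type and 39.6 CPM in cre) and expression by the B1b cells themselves, with 22 of the 28 genes above 0, cannot be told apart from this, since bulk libraries do not say which cell held a transcript.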
